A study of Homo sapiens with 16 samples.

How the data were processed

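A549 cells were analysed on 16 2-colour microarrays, 4 for each of 4 groups (miR-210, miR-34a, siE2F3 and siCT). Each array set RNA of transfected cells against RNA of cells given the negative control microRNA (miR-Neg) in the same experiment. Per the labels, RNA was extracted with Trizol 48 h after transfection and labelled with Cy3 and Cy5, and the series text gives 2 independent experiments, each in dye swap. The values used are the log ratios the authors deposited, 1 per feature and array, for 27648 features with no missing value. Their unit was read as log2, since the deposited values run from −5.78 to 5.99, although no source used here states the base. Base 10 would give ratios beyond what such arrays measure, and a natural logarithm could not be ruled out, in which case folds would be larger than stated. Each deposited array has a mean of 0, which points to centring by the authors. Array medians lie between −0.019 and 0.024 and array SDs between 0.24 and 0.469. The background correction, the normalization within arrays and the software of the authors are not given in the sources used here. No intensities were used, so dim probes and control spots could not be filtered, and signal over background is unknown.

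The direction of the ratios is not stated either. The 2 arrays of every dye swap correlated above 0 (r between 0.07 and 0.5 across features), so the deposited ratios had already been turned one way. The lowest r belonged to siCT, in both experiments. The reading as transfected over miR-Neg is likely, from E2F3 under its own siRNA, NDUFA4 and SDHD under miR-210 and CDK4 under miR-34a. Across the 24484 rows described below, with dye swaps averaged, the 2 experiments of a group correlated at r = 0.53 (miR-210), 0.64 (miR-34a), 0.45 (siE2F3) and 0.33 (siCT).

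Features were named through the platform annotation, which gave 1 gene symbol for 17711 features, several for 0 and none for 9937. Symbols were updated with the RefSeq gene table of assembly GRCh38.p14. Of the named features, 14718 were updated through a RefSeq accession, 1808 already had a current symbol, 1029 were set through a unique synonym and 156 kept the platform symbol. Features of a gene were averaged, which gave 14547 genes, 2057 of them with more than 1 feature. ACTB had 321 and GAPDH 272 features, and whether these are control spots is not stated in the sources used here. Unnamed features stayed in the test by themselves but out of gene lists. This gave 24484 rows. Columns of other samples numbered 0.

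The 2 arrays of a dye swap were averaged to 1 replicate, so n = 2 per group. All 8 replicates entered 1 linear model (limma 3.58.1 in R 4.3.3, lmFit and eBayes), because 2 replicates alone give 1 degree of freedom. The model had 4 residual degrees of freedom, a prior SD of 0.138 and 3.24 prior degrees of freedom. Each group mean was tested against 0, and siE2F3 against siCT and miR-34a against miR-210 as differences, with two-sided tests and a Benjamini-Hochberg adjusted p threshold of 0.05 over the 24484 rows. A test against 0 takes in the spread of the miR-Neg RNA only as its difference between the 2 experiments. All groups of an experiment share that RNA, so their errors are not independent. Array numbers in the labels do not follow the experiments throughout. The siE2F3 arrays of experiment 2 are numbered with the experiment 1 arrays of the other groups. Batches within an experiment were not tested.

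The rule for named genes was E2F3 in every comparison, then, among named genes past the threshold with one sign on all arrays of a group (in both experiments for differences), the 8 highest and 8 lowest, and the 2 to 4 members of each described list with the largest size, called ones first. The text does not follow the last part throughout, since a list member may be named where a larger one is not. Of the highest and lowest genes, 1 is not named in the text, and the counts include it. The 19 gene lists covered the E2F family, G1/S and DNA replication, G2/M and mitosis, p53 targets, reported miR-34a targets, reported miR-210 targets, respiratory chain complex I, complexes II to V, iron and iron-sulfur metabolism, hypoxia targets, the interferon and double-stranded RNA response, NF-kB and inflammatory cytokines, cholesterol synthesis, the unfolded protein and amino acid stress response, the epithelial and mesenchymal state, microRNA machinery, ribosomal proteins, blood and immune cell markers, and fibroblast and endothelial markers. Some genes belong to several lists. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 19 lists of a comparison. With the correlation estimated from the data, 0 of the 42 list results called among 114 passed, and that adjusted p is given beside each. Members were also tested with the adjustment over the list alone. For every called list the median, the mean and the test had one sign. The groups, tests, gene lists, the rule for named genes and the alternatives were set before the data were examined, except those that the closing section names as added later.

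On data simulated for miR-210 against miR-Neg (24484 rows), the model recovered 38% of changes of 0.5 and 86% of changes of 1 on the log2 scale, with 12 false calls. Only 100 rows were changed at each size, in miR-210 alone, and the simulated groups shared no miR-Neg noise. Recovery and false calls in the data may therefore differ. A list shifted by −0.3, that of G2/M and mitosis, had a camera adjusted p of 2.223e-28, and 0 other lists were called. The simulated rows were independent, while the estimated correlation of that list in the data was 0.33. False list calls among correlated genes were therefore not tested by this simulation. Overlaps between groups that share the miR-Neg RNA were set beside 20 simulated draws of unchanged groups. The series text describes 2 independent experiments and each has its own miR-Neg RNA, so replicate numbers pair samples across groups. The deviations of same-numbered replicates from their group means correlated at 0.08 to 0.20 across rows. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

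Alternatives were median centring, scaling and quantile normalization of arrays, all 16 arrays with the RNA pair as a random block and a dye term, arrays of one dye orientation, the experiment as a block, the compared groups alone in the fit, leaving out each replicate, siCT as the control, leaving out the 25% least variable rows, single probes, NDUFA4 counted with complexes II to V, robust or no moderation, named rows alone and an estimated correlation. An analysis of microRNA seed sites was not run, since no 3′ UTR sequences were used here.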

Results

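Gene expression was measured on 16 2-colour microarrays in A549 cells, an established human lung adenocarcinoma line, 48 h after transfection with a small RNA duplex. The cells received miR-210, a microRNA induced by hypoxia, miR-34a, a microRNA induced by p53, an siRNA against the cell cycle transcription factor E2F3 (siE2F3), or a control siRNA (siCT). Each of these 4 groups was hybridised against RNA of cells given a negative control microRNA (miR-Neg) in the same experiment. There were 2 independent experiments, each with a dye swap, so every group had 4 arrays. The 2 arrays of a dye swap shared their RNA and were averaged, which left n = 2 replicates per group. Values are log2 ratios, read as transfected over miR-Neg. Errors are standard errors (SE) of the limma fit, with n = 2 per group, unless an SD or an SE over genes is named. The number of arrays limits the precision, since the median SE of a gene was 0.099 against miR-Neg and 0.14 for a difference between groups. All groups of an experiment shared one miR-Neg RNA, so their errors against miR-Neg were not independent. The spread of that control entered the tests only as its difference between the 2 experiments.

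E2F3 itself was lower on all 4 siE2F3 arrays, at −1.37 and −1.40 in experiment 1 and −1.02 and −0.98 in experiment 2. The mean of −1.19 ± 0.10 left 43.8% of the miR-Neg level (limma adjusted p = 0.0043). Under miR-210, for which E2F3 is a reported target, the gene was higher on all 4 arrays (0.39 to 0.49), with a mean of 0.43 ± 0.10 (limma adjusted p = 0.045). Under miR-34a, another microRNA reported to target it, the 4 arrays lay between −0.24 and −0.15, and the mean of −0.19 ± 0.10 did not pass the test (limma adjusted p = 0.30). The siCT arrays lay above 0 too, from 0.17 to 0.35 (0.26 ± 0.10, limma adjusted p = 0.38). Against siCT, the difference of miR-210 was thus smaller than against miR-Neg, and that of miR-34a larger. Set against siCT, E2F3 was lower in siE2F3 by −1.45 ± 0.14 (limma adjusted p = 0.014). The deposited ratios do not state their direction. The reading as transfected over miR-Neg is likely, on the basis of E2F3 under its own siRNA, NDUFA4 and SDHD under miR-210, and CDK4 under miR-34a. With the sign turned, higher and lower would swap throughout.

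**Figure D1:**
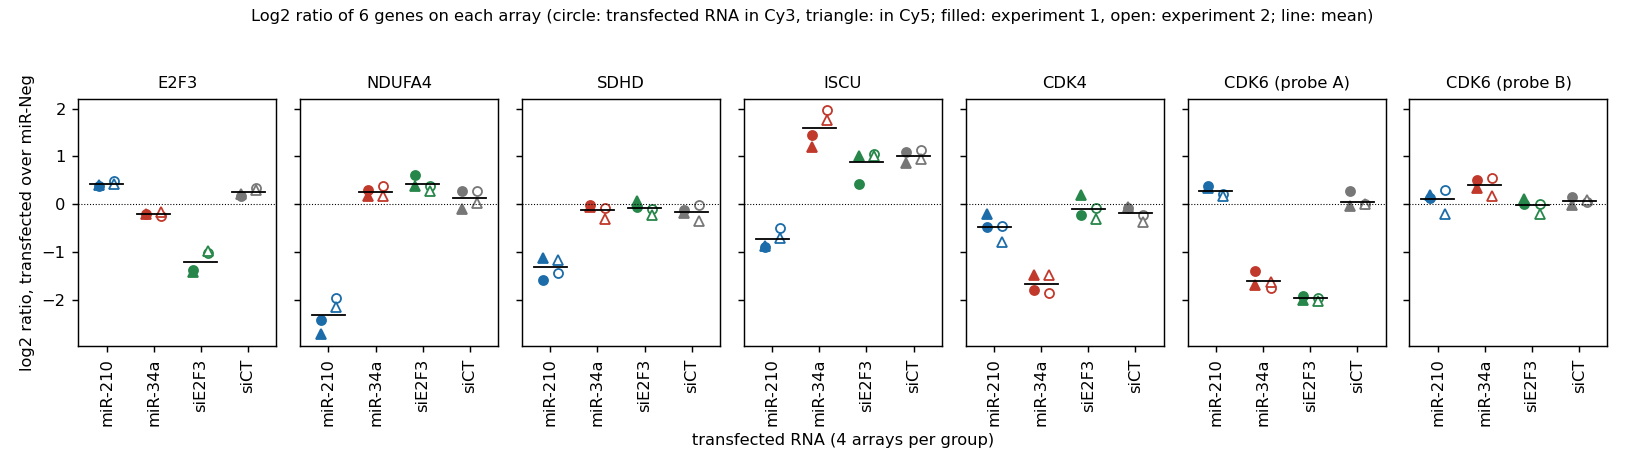
Log2 ratio (transfected over miR-Neg, vertical axis) of 6 genes on each array of the 4 groups (horizontal axis), with CDK6 shown for each of its 2 probes. Circles are arrays with the transfected RNA in Cy3, triangles in Cy5, filled symbols experiment 1, open symbols experiment 2 and lines the group means: E2F3 lies between −1.40 and −0.98 on the siE2F3 arrays, NDUFA4 between −2.71 and −1.95 on the miR-210 arrays, and the CDK6 probes part under miR-34a (−1.60 and 0.40).

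The first comparison asked which transcripts differed under miR-210. The gene with the highest ratio was IL11, a cytokine of the interleukin-6 family, at 3.72 ± 0.34, a 13.2-fold rise. NT5E, the ectoenzyme that makes extracellular adenosine (2.13 ± 0.07), SFRP1, a secreted Wnt antagonist (2.04 ± 0.16), the growth factor gene CSF2 (1.93 ± 0.32) and the glucose transporter gene SLC2A3 (1.88 ± 0.22) also rose. The gene with the lowest ratio was NDUFA4 (current symbol COXFA4), a subunit of the respiratory chain, at −2.30 ± 0.12, a 4.92-fold fall. LASP1, which binds actin (−2.06 ± 0.11), the haem-degrading enzyme HMOX1 (−2.01 ± 0.24), SH3BGRL (−1.97 ± 0.09) and the antimicrobial peptide DEFB1 (−1.93 ± 0.10) fell as well. Further genes of the highest set were PGM2L1 (1.83 ± 0.15), WNT10B (1.73 ± 0.27) and TMEM158 (1.66 ± 0.15). AATF (−1.86 ± 0.11), SCARA3 (−1.82 ± 0.15) and ALDH3B1 (−1.76 ± 0.13) completed the lowest set. All of these had limma adjusted p of 0.015 or lower and one sign on all 4 arrays. HMOX1 was also low in siCT, at −1.31 ± 0.24 (limma adjusted p = 0.089, not past the threshold), so its fall is not particular to miR-210.

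Of 45 measured genes among 50 reported miR-210 targets, 10 fell and 5 rose under miR-210. Adjusted over the list alone, 18 fell and 6 rose. The list median was −0.17 (camera adjusted p = 0.011), and adjusted p = 0.28 with an estimated correlation. NDUFA4, SDHD, a membrane anchor of succinate dehydrogenase (−1.31 ± 0.08), and the ribosomal RNA methyltransferase gene DIMT1 (−0.93 ± 0.08) fell, and NPTX1, a pentraxin, rose (1.04 ± 0.23). Some of these targets, NDUFA4 and SDHD among them, may have been reported from work on these samples, so the list is not independent evidence of its direction. Against siCT in place of miR-Neg, the list median was −0.06 and no longer passed (camera adjusted p = 0.061).

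The respiratory chain lists moved both ways under miR-210. In complex I, 4 of 37 measured genes rose and 5 fell (median −0.04, camera adjusted p = 0.78), with NDUFA11 at −1.05 ± 0.14, NDUFA10 at −0.64 ± 0.09 and NDUFB4 at 0.65 ± 0.11. The complex I list holds NDUFA4, which is now assigned to complex IV, and counting it with complexes II to V changed no camera call of either list in the 6 comparisons. In complexes II to V, 3 of 45 rose and 5 fell (median 0.07, camera adjusted p = 0.64), and the ATP synthase gene ATP5F1D was at −0.72 ± 0.10. Among 26 iron and iron-sulfur genes, 3 rose and 5 fell (median −0.01, camera adjusted p = 0.64). The iron transporter gene SLC11A2 rose by 1.26 ± 0.09, and the transferrin receptor gene TFRC (−0.86 ± 0.17) and FDXR, which passes electrons for iron-sulfur assembly (−0.90 ± 0.09), fell. Of 41 hypoxia genes, 6 rose and 2 fell (median 0.08, camera adjusted p = 0.12), and adjusted p = 0.92 with an estimated correlation. The list median was 0.26 without experiment 1 of miR-210. SLC2A3, the lipase inhibitor gene ANGPTL4 (1.54 ± 0.12) and the collagen hydroxylase gene P4HA2 (0.99 ± 0.13) were among those that rose, whereas the carbonic anhydrase gene CA12 fell (−1.29 ± 0.10).

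Of 24 NF-kB and inflammatory cytokine genes, 4 rose and 1 fell, with a median of 0.18 (camera adjusted p = 0.019), and adjusted p = 0.92 with an estimated correlation. CSF2, the chemokine gene CXCL8 (1.52 ± 0.33) and IL32 (0.94 ± 0.17) rose, and CXCL1 fell (−1.37 ± 0.25). Adjusted over the list alone, 8 rose and 1 fell. The median was 0.02 without experiment 2 of miR-210 (camera adjusted p = 0.97) and 0.53 without experiment 1 (7.1e-05). Cholesterol synthesis genes had a median of 0.21 (camera adjusted p = 0.011), and adjusted p = 0.92 with an estimated correlation. Of its 20 measured genes, 5 rose and 1 fell, and 9 rose and 3 fell adjusted over the list alone. IDI1 (1.0 ± 0.2), STARD4 (0.80 ± 0.09) and the squalene epoxidase gene SQLE (0.75 ± 0.17) rose. Of 37 interferon and double-stranded RNA response genes, 3 fell and none of the others passed the limma test, both over all genes and adjusted over the list alone. The median was −0.12 (camera adjusted p = 0.035), and adjusted p = 0.92 with an estimated correlation, and it was −0.22 without experiment 2 of miR-210 (camera adjusted p = 0.038). IFI35 (−0.86 ± 0.20), PSMB9 (−0.63 ± 0.14) and the RNA sensor gene TLR3 (−0.62 ± 0.09) were the 3 genes. Of 48 reported miR-34a targets, 8 rose and 2 fell under miR-210 (10 and 2 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.019), and adjusted p = 0.42 with an estimated correlation. ULBP2, a ligand of natural killer cells (1.27 ± 0.09), E2F5 (1.0 ± 0.2) and the kinase gene MAP2K1 (0.90 ± 0.14) rose, and the activin subunit gene INHBB fell (−1.33 ± 0.19). The interferon, cholesterol and miR-34a target lists lost their calls without experiment 1 of miR-210 (camera adjusted p = 0.29, 0.23 and 0.20). None of the 3, nor the NF-kB list, was called against siCT (camera adjusted p between 0.061 and 0.13).

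In all, 2019 of 24484 rows (genes, and probes without a gene name) passed limma's adjusted p of 0.05 under miR-210. Of these, 1041 were higher and 978 lower, and 217 differed by more than 1 on the log2 scale. The count was 1223 without experiment 1 of miR-210 and 754 without experiment 2, and 438 with siCT as the control. With the other 3 groups left out of the fit, limma called 0 rows, and 4153 had an unadjusted p under 0.05.

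The second comparison asked the same of miR-34a. OSGIN2 had the highest ratio (2.50 ± 0.12, 5.66-fold). It was followed by the hexosamine pathway gene GFPT2 (2.41 ± 0.11), the mitochondrial cyclophilin gene PPIF (2.39 ± 0.16), PHLDA2 (2.32 ± 0.12) and CXCL8 (2.25 ± 0.33). The chaperone gene HSP90AA1 (2.17 ± 0.34), the tubulin gene TUBB2A (2.15 ± 0.13) and the interferon-induced gene IFIT1 (2.15 ± 0.29) rose as well. LITAF had the lowest ratio (−2.46 ± 0.31, 5.48-fold). INSL4, an insulin-like peptide (−2.27 ± 0.18), ID1, an inhibitor of basic helix-loop-helix factors (−2.26 ± 0.28), NAA50 (−1.95 ± 0.09) and the nuclear pore gene NUP210 (−1.95 ± 0.12) fell. TMUB1 (−1.91 ± 0.12) and the sodium pump subunit gene ATP1B3 (−1.90 ± 0.12) were also among the lowest. All had limma adjusted p of 0.0078 or lower. The 2 IFIT1 probes were at 1.49 and 2.80, and GFPT2 rose in the other 3 groups too (0.83 to 1.02).

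Cell cycle genes fell under miR-34a. Of 48 measured genes of G2/M and mitosis, 33 fell and none rose past the limma threshold over all genes (38 fell and 1 rose adjusted over the list alone). Their median was −0.66 (camera adjusted p = 8.4e-21), and adjusted p = 0.21 with an estimated correlation. The kinase gene AURKB (−1.79 ± 0.22), cyclin B gene CCNB1 (−1.56 ± 0.31), securin gene PTTG1 (−1.50 ± 0.14) and HMMR (−1.36 ± 0.19) had the lowest values. Of 50 genes of G1/S and DNA replication, 28 fell and none rose past that threshold (30 and 0 adjusted over the list alone), with a median of −0.50 (camera adjusted p = 4e-16), and adjusted p = 0.21 with an estimated correlation. TK1 (−1.73 ± 0.22), the replication licensing genes MCM2 (−1.60 ± 0.10) and GMNN (−1.58 ± 0.13) and cyclin A gene CCNA2 (−1.51 ± 0.10) fell. In the E2F family, E2F2 fell (−0.64 ± 0.10) and the other 10 measured genes did not pass (median −0.23, camera adjusted p = 0.092). With an estimated correlation that list had a camera adjusted p of 0.52, and its median was −0.24 without experiment 2 of miR-34a.

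Of 48 measured genes among 49 reported miR-34a targets, 9 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of −0.15 (camera adjusted p = 0.0019), and adjusted p = 0.21 with an estimated correlation. The cell cycle kinase gene CDK4 (−1.65 ± 0.10), RRAS (−0.77 ± 0.10) and the deacetylase gene SIRT1 (−0.69 ± 0.12) fell. CDK6 had 2 probes that disagreed, at −1.60 and 0.40. Among 30 p53 targets, 13 rose and 2 fell (14 and 4 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00099), and adjusted p = 0.24 with an estimated correlation. The p53 median was 0.19 without experiment 1 of miR-34a (camera adjusted p = 0.030). SFN, the stratifin gene (2.14 ± 0.13), and the pro-apoptotic genes BBC3 (1.44 ± 0.16) and PMAIP1 (1.39 ± 0.18) rose, whereas the cyclin G gene CCNG1 fell (−1.75 ± 0.20).

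Interferon and double-stranded RNA response genes rose under miR-34a. Of 37 measured genes 23 rose and none fell past the limma threshold (28 and 0 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 4.3e-15), and adjusted p = 0.26 with an estimated correlation. IFIT1, the ubiquitin-like gene ISG15 (2.05 ± 0.40), IFIT2 (1.94 ± 0.35) and IFIT3 (1.84 ± 0.34) had the highest values. Of 24 NF-kB and cytokine genes 7 rose and none fell past it (10 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.5e-05), and adjusted p = 0.49 with an estimated correlation. This median was 0.55 without experiment 1 of miR-34a (camera adjusted p = 3.9e-10) and 0.13 without experiment 2, where the list was not called (0.068). CXCL8, IL32 (1.93 ± 0.17), and the chemokine genes CCL2 (1.83 ± 0.33) and CCL20 (1.25 ± 0.29) rose. Of 26 iron and iron-sulfur genes, 9 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 5e-05), and adjusted p = 0.21 with an estimated correlation. SLC11A2 (2.08 ± 0.09), the iron-sulfur scaffold gene ISCU (1.59 ± 0.14), the iron exporter gene SLC40A1 (1.45 ± 0.09) and FECH, the last enzyme of haem synthesis (0.99 ± 0.08), rose. ISCU was also high in siCT, at 1.01 (not past the limma threshold), so its rise is not particular to miR-34a.

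Of 41 hypoxia genes, 10 rose and 3 fell under miR-34a (14 and 4 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0021), and adjusted p = 0.49 with an estimated correlation. ENO2 (1.27 ± 0.21), STC2 (1.25 ± 0.20) and P4HA2 (1.13 ± 0.13) rose, and the glycolytic gene TPI1 fell (−1.11 ± 0.17). Of 45 genes of complexes II to V, 9 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0018), and adjusted p = 0.29 with an estimated correlation. COX6B1 (0.56 ± 0.15) and SDHC (0.54 ± 0.12) rose. Of 37 complex I genes, 6 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.030), and adjusted p = 0.49 with an estimated correlation. NDUFA6 (1.02 ± 0.11) and NDUFV2 (0.68 ± 0.16) rose, and NDUFB11 fell (−0.50 ± 0.07). Without experiment 1 of miR-34a the hypoxia and complex I lists were not called (medians 0.12 and 0.07, camera adjusted p = 0.096 and 0.21).

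Under miR-34a, 3010 of 24484 rows passed limma's adjusted p of 0.05, 1637 higher and 1373 lower, and 394 by more than 1 on the log2 scale. The count was 1801 without experiment 1 of miR-34a and 1094 without experiment 2, and 986 with siCT as the control. With the other 3 groups left out of the fit it was 788.

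**Figure D2:**
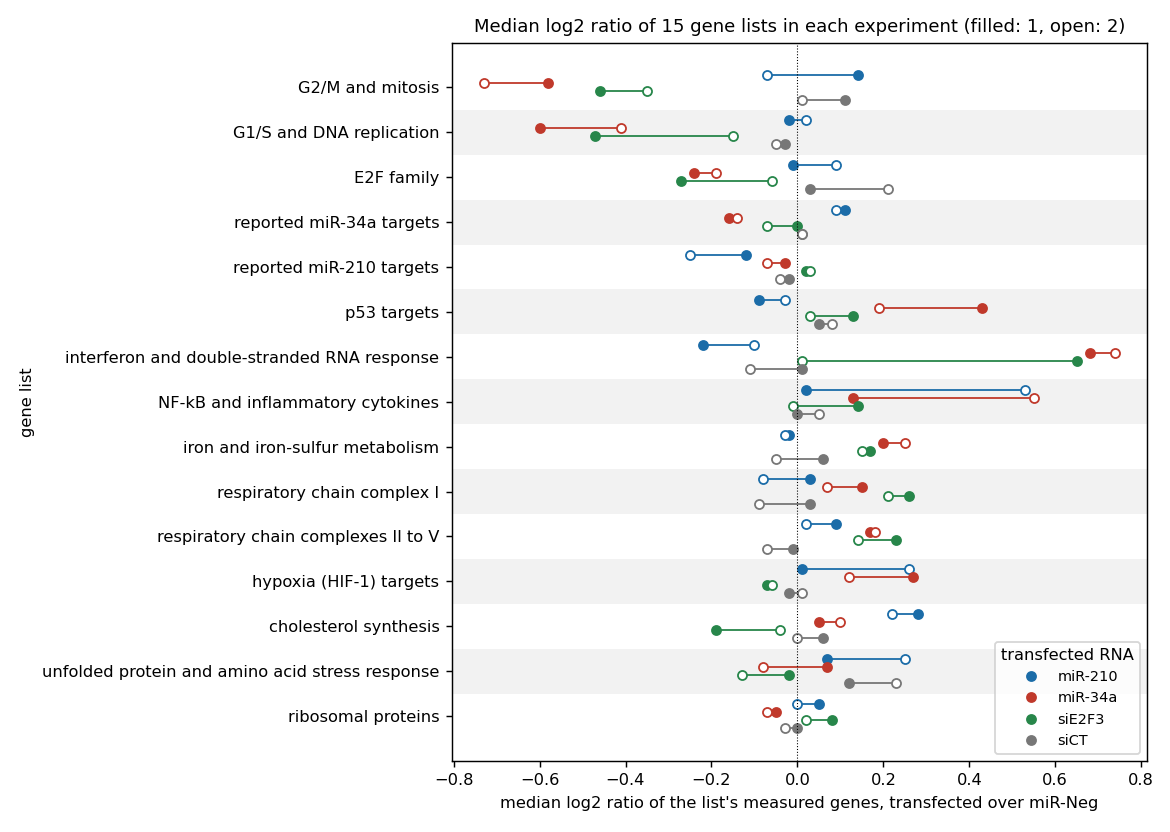
Median log2 ratio (transfected over miR-Neg, horizontal axis) of the measured genes of 15 gene lists (vertical axis) in the 4 groups, with filled points for experiment 1, open points for experiment 2 and a line joining them. Under miR-34a the G2/M and G1/S lists lie lowest and the interferon list highest, with medians over both experiments of −0.66, −0.50 and 0.74, while the siE2F3 interferon points lie apart at 0.65 and 0.01.

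The third comparison asked which transcripts differed under siE2F3. No other siRNA against E2F3 was measured, so effects of E2F3 loss and other effects of this siRNA cannot be told apart. The lowest genes under siE2F3, lower than E2F3 itself, were the mitochondrial ferredoxin gene FDX1 (−1.70 ± 0.11), the matricellular gene CCN1 (−1.69 ± 0.24), the EGF receptor ligand gene EREG (−1.66 ± 0.17) and the thioredoxin reductase gene TXNRD1 (−1.51 ± 0.18). SDHC, a subunit of succinate dehydrogenase (−1.45 ± 0.12), the DNA repair exonuclease gene EXO1 (−1.45 ± 0.13), the chemokine gene CXCL5 (−1.43 ± 0.12) and DEFB1 (−1.40 ± 0.10) followed. The highest genes were RDX, which links actin to the membrane (1.82 ± 0.09), the synaptic vesicle gene SYNGR3 (1.79 ± 0.15), UBE2V1 (1.69 ± 0.17), the splicing factor gene SNRPC (1.49 ± 0.11) and the GABA receptor gene GABRA5 (1.27 ± 0.14). SLC35A1 (1.25 ± 0.08), PJA1 (1.19 ± 0.13) and STEAP3, a metalloreductase (1.18 ± 0.13), completed that set. All had limma adjusted p of 0.018 or lower. RDX, UBE2V1, SNRPC and SLC35A1 also rose in the other 3 groups.

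The cell cycle lists had medians below 0 under siE2F3 as well, though few of their genes passed the limma threshold over all genes. Of 48 G2/M genes 8 fell and none rose past the limma threshold (25 and 0 adjusted over the list alone), with a median of −0.36 (camera adjusted p = 5.2e-17), and adjusted p = 0.29 with an estimated correlation. The centromere gene CENPA (−1.11 ± 0.11), STMN1, which destabilises microtubules (−1.0 ± 0.2), DLGAP5 (−0.88 ± 0.14) and CEP55 (−0.80 ± 0.12) fell. Of 50 G1/S genes 6 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 1.4e-09), and adjusted p = 0.34 with an estimated correlation. The G1/S median was −0.15 without experiment 1 of siE2F3 (camera adjusted p = 0.012) and −0.47 without experiment 2 (5.8e-16). The ribonucleotide reductase gene RRM2 (−1.01 ± 0.14), GINS2 (−0.89 ± 0.16) and CCNA2 (−0.79 ± 0.10) fell. Of 11 E2F family genes, E2F3 and its partner TFDP1 (−0.74 ± 0.14) fell and none rose past the threshold, over all genes and adjusted over the list alone (median −0.24, camera adjusted p = 0.0048), and adjusted p = 0.40 with an estimated correlation. Without experiment 1 of siE2F3 that list was not called (median −0.06, camera adjusted p = 0.23). CDK6 was at −1.96 on one probe and −0.02 on the other.

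Both respiratory chain lists had medians above 0 under siE2F3, though few of their genes passed the limma threshold over all genes. In complex I, 4 of 37 rose and none fell past the limma threshold (17 and 0 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.4e-08), and adjusted p = 0.29 with an estimated correlation. NDUFA6 (1.13 ± 0.11) and NDUFA8 (0.54 ± 0.09) rose. In complexes II to V, 5 of 45 rose and 1, SDHC, fell (17 and 2 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 1.3e-06), and adjusted p = 0.29 with an estimated correlation. The assembly factor gene SURF1 (0.61 ± 0.08) and COX7A2 (0.60 ± 0.10) rose. Of 26 iron and iron-sulfur genes, 5 rose and 1, FDX1, fell (9 and 2 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.019), and adjusted p = 0.29 with an estimated correlation. SLC11A2 (1.18 ± 0.09), ISCU (0.88 ± 0.14) and FDXR (0.76 ± 0.09) rose, and ISCU was no lower in siCT (1.01, not past the limma threshold).

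Of 37 interferon genes 3 rose and none fell past the limma threshold under siE2F3 (12 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 2.3e-06), and adjusted p = 0.54 with an estimated correlation. IRF9 (0.89 ± 0.15), the RNA sensor gene RIGI (0.79 ± 0.13) and OAS2 (0.52 ± 0.10) rose, OAS2 with its 2 probes at 0.05 and 0.99, and ISG15 was at 1.75 ± 0.40 (limma adjusted p = 0.068). The list median was 0.65 in experiment 1 and 0.01 in experiment 2, and without experiment 1 the list was not called (camera adjusted p = 0.64). The iron list also lost its call without experiment 1 (median 0.15, camera adjusted p = 0.23).

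Under siE2F3, 774 of 24484 rows passed limma's adjusted p of 0.05, 437 higher and 337 lower, and 96 by more than 1 on the log2 scale. The count was 432 without experiment 1 of siE2F3 and 143 without experiment 2, and the share of higher rows, 56.5% of the 774, was 38.7% and 39.2% there. With the other 3 groups left out of the fit limma called 0, and 3994 had an unadjusted p under 0.05.

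The siCT arrays gave the difference between the 2 kinds of control. The hyaluronidase gene CEMIP2 (1.67 ± 0.13), SNRPC (1.45 ± 0.11), UBE2V1 (1.31 ± 0.17) and the hydroxylase gene ASPH (1.31 ± 0.10) were highest, ASPH with 5 probes between 0.37 and 2.37. The fibrinogen gene FGA (1.24 ± 0.11), COMMD10 (1.23 ± 0.16), PDCD4, a translation inhibitor (1.22 ± 0.16), and ERLIN1 (1.16 ± 0.09) rose as well. CHP (−1.15 ± 0.13), PRELID1 (−1.03 ± 0.09), the splicing gene SNRNP27 (−0.98 ± 0.11), the extracellular matrix gene EFEMP1 (−0.86 ± 0.08), DHX40 (−0.83 ± 0.11), BLTP2 (−0.78 ± 0.07), LSM7 (−0.77 ± 0.07) and LXN (−0.76 ± 0.10) were lowest. All had limma adjusted p of 0.039 or lower, and 22 of the 80 rows called were called the same way in the other 3 groups.

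Among the lists, the unfolded protein and amino acid stress response had a median of 0.18 in siCT (camera adjusted p = 0.00076), and adjusted p = 0.82 with an estimated correlation. None of its 28 measured genes passed limma over all genes, and 4 rose adjusted over the list alone. DNAJB9 was at 0.76 ± 0.15 (limma adjusted p = 0.11) and PSAT1 at 0.59 ± 0.10 (limma adjusted p = 0.080). The interferon (median −0.04), G2/M (0.12) and G1/S (−0.02) lists were not called in siCT (camera adjusted p = 0.88, 0.22 and 0.79). ISCU was at 1.01 ± 0.14 (limma adjusted p = 0.050, not past the threshold), beside 1.59 under miR-34a and 0.88 under siE2F3.

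The 80 rows that passed limma's adjusted p of 0.05 in siCT were 55 higher and 25 lower, 21 of them by more than 1 on the log2 scale. Without experiment 1 of siCT the count was 284, and without experiment 2 limma called 0, where 1804 had an unadjusted p under 0.05. It was 128 with the experiment as a block, and 0 with the other 3 groups left out of the fit, where 2774 had an unadjusted p under 0.05.

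The control siRNA is the closer control of siE2F3, and the miR-Neg RNA cancels from their difference. Against siCT, SYNGR3 (2.21 ± 0.21), DHX40 (1.69 ± 0.15), STEAP3 (1.58 ± 0.18), the retinol carrier gene RBP4 (1.54 ± 0.21) and OSGIN2 (1.51 ± 0.17) were highest in siE2F3. TOP1MT, the mitochondrial topoisomerase gene (1.48 ± 0.12), SNRNP27 (1.34 ± 0.16) and EMP2 (1.32 ± 0.21) followed. CCN1 (−2.52 ± 0.34), EREG (−2.46 ± 0.24), CEMIP2 (−2.12 ± 0.19) and the zinc transporter gene SLC39A14 (−2.06 ± 0.23) were lowest, with TM4SF1 (−1.76 ± 0.17), FGA (−1.74 ± 0.15), FDX1 (−1.73 ± 0.15) and the RNA polymerase subunit gene POLR2D (−1.55 ± 0.13). All had limma adjusted p of 0.042 or lower. CEMIP2, FGA, DHX40 and SNRNP27 were among the genes that differed between siCT and miR-Neg.

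The G2/M list was lower in siE2F3 than in siCT, with a median of −0.47 (camera adjusted p = 1.2e-14), and adjusted p = 0.35 with an estimated correlation. CEP55 (−1.20 ± 0.17) and CENPA (−0.89 ± 0.15) fell and none rose over all genes, and 16 fell and 1 rose adjusted over the list alone. The G1/S list had a median of −0.25 (camera adjusted p = 4.7e-05), and adjusted p = 0.48 with an estimated correlation. CCNA2 (−1.22 ± 0.15) and RRM2 (−1.21 ± 0.19) fell and the DNA methyltransferase gene DNMT1 rose (0.82 ± 0.14), and 3 fell and 1 rose adjusted over the list alone. The E2F family had a median of −0.27 (camera adjusted p = 0.00065), and adjusted p = 0.36 with an estimated correlation, with 1 of its 11 genes, E2F3, lower over all genes and 2 adjusted over the list alone. Its median was −0.18 without experiment 1 of siE2F3, −0.43 without experiment 2 and −0.42 without experiment 1 of siCT (camera adjusted p of 0.032 or lower). That of G1/S was −0.38 without experiment 2 of siE2F3 (camera adjusted p = 2.7e-09) and −0.13 without experiment 1, where it was not called (0.18). Complex I had a median of 0.28 (camera adjusted p = 8.5e-07), and adjusted p = 0.35 with an estimated correlation. NDUFA5 (1.07 ± 0.10) and NDUFA3 (0.75 ± 0.11) rose, and 10 rose adjusted over the list alone. Complexes II to V had a median of 0.20 (camera adjusted p = 4.7e-05), and adjusted p = 0.35 with an estimated correlation. SURF1 rose (0.84 ± 0.12) and SDHC fell (−1.36 ± 0.17), and 7 rose and 1 fell adjusted over the list alone.

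The interferon list was higher in siE2F3 than in siCT (median 0.35, camera adjusted p = 0.00011), and adjusted p = 0.54 with an estimated correlation. None of its genes passed limma over all genes and 5 rose adjusted over the list alone, with ISG15 at 1.82 ± 0.56 (limma adjusted p = 0.20). The stress response list was lower (median −0.25, camera adjusted p = 0.00032), and adjusted p = 0.35 with an estimated correlation, with no gene past limma over all genes, 1 that rose adjusted over the list alone, and EDEM1 at −0.86 ± 0.25. The cholesterol list was lower (median −0.19, camera adjusted p = 0.032), and adjusted p = 0.54 with an estimated correlation, with no gene past limma on either adjustment and IDI1 at −0.81 ± 0.24. The interferon median was 0.60 without experiment 2 of siE2F3 (camera adjusted p = 1.9e-15). Without its experiment 1 the interferon and cholesterol lists were not called (medians 0.07 and −0.13, camera adjusted p = 0.40 each), nor the stress list without its experiment 2 (0.087) or the cholesterol list without experiment 1 of siCT (0.40).

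In this comparison 299 rows passed limma's adjusted p of 0.05, 152 higher and 147 lower, and 125 by more than 1 on the log2 scale. Without experiment 1 of siCT the count was 193, and without experiment 2 of siE2F3 it was 16. Without experiment 2 of siCT limma called 0 (2530 rows with an unadjusted p under 0.05), as it did with only siE2F3 and siCT in the fit (3650 such rows).

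The last comparison tested the difference between the 2 microRNAs. The aldehyde dehydrogenase gene ALDH3A1 (3.11 ± 0.37, 8.65-fold), the matrix metalloproteinase gene MMP7 (3.01 ± 0.20), SFN (2.96 ± 0.19), HMOX1 (2.78 ± 0.35) and NDUFA4 (2.56 ± 0.17) were higher under miR-34a than under miR-210. IFIT2 (2.54 ± 0.50), CIG41 (2.50 ± 0.46) and OSGIN2 (2.46 ± 0.17) completed the highest set. ATP1B3 (−2.31 ± 0.17), INSL4 (−2.17 ± 0.25), FGA (−2.06 ± 0.15), GABRA5 (−1.92 ± 0.20) and the lymphangiogenic factor gene VEGFC (−1.90 ± 0.14) were lower under miR-34a. SH3PXD2B (−1.89 ± 0.11) and GMNN (−1.89 ± 0.18) followed. All had limma adjusted p of 0.035 or lower. E2F3 was lower under miR-34a by −0.63 ± 0.14, which did not pass (limma adjusted p = 0.055).

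The G2/M list was lower under miR-34a than under miR-210, with 19 of 48 genes lower and none higher past the limma threshold (33 and 1 adjusted over the list alone). Its median was −0.69 (camera adjusted p = 2.8e-19), and adjusted p = 0.17 with an estimated correlation. PTTG1 (−1.57 ± 0.20) and KIF4A (−1.17 ± 0.12) were among them. The G1/S list had 11 of 50 genes lower and none higher past the threshold (25 and 0 adjusted over the list alone), with GMNN and the primase gene PRIM1 (−1.59 ± 0.27) lowest. Its median was −0.49 (camera adjusted p = 4.3e-14), and adjusted p = 0.17 with an estimated correlation. The interferon list had 14 of 37 genes higher and none lower past the threshold (27 and 0 adjusted over the list alone), with IFIT2, IFIT1 (2.45 ± 0.41) and IFIT3 (2.33 ± 0.48) highest. Its median was 0.90 (camera adjusted p = 5.4e-17), and adjusted p = 0.19 with an estimated correlation. Among p53 targets 3 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 2.3e-05), and adjusted p = 0.16 with an estimated correlation. SFN, the kinase gene PLK2 (1.68 ± 0.32) and FDXR (1.26 ± 0.12) were higher and CCNG1 (−1.36 ± 0.28) lower.

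Reported miR-34a targets were lower under miR-34a than under miR-210, with 12 of 48 lower and none higher past the threshold (16 and 2 adjusted over the list alone). Their median was −0.23 (camera adjusted p = 6.4e-07), and adjusted p = 0.074 with an estimated correlation. E2F5 (−1.63 ± 0.24), ULBP2 (−1.42 ± 0.13) and CDK4 (−1.17 ± 0.14) were among them. Against miR-Neg, ULBP2 (1.27) and E2F5 (1.0) rose under miR-210, while the 3 ULBP2 probes lay between −0.22 and −0.08 under miR-34a. The differences of these 2 genes thus hold a rise under miR-210. Reported miR-210 targets were higher under miR-34a, with 8 of 45 higher and none lower past the threshold (11 and 3 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.0072), and adjusted p = 0.15 with an estimated correlation. This median was 0.08 without experiment 2 of miR-210 and 0.21 without experiment 2 of miR-34a (camera adjusted p = 0.0092 and 0.0029). NDUFA4, ISCU (2.32 ± 0.20), SDHD (1.20 ± 0.11) and the mitophagy gene BNIP3 (1.16 ± 0.20) were among them. Of 26 iron and iron-sulfur genes 8 were higher and none lower past the threshold (9 and 0 adjusted over the list alone), with HMOX1 and ISCU highest and SLC40A1 at 1.15 ± 0.13. The median was 0.25 (camera adjusted p = 1.1e-06), and adjusted p = 0.074 with an estimated correlation.

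Both respiratory chain lists were higher under miR-34a. Complex I had a median of 0.14 (camera adjusted p = 0.012), and adjusted p = 0.43 with an estimated correlation, with NDUFA11 (1.09 ± 0.21) and NDUFA4, which that list holds, higher on either adjustment. Without NDUFA4 the median was 0.14 (camera adjusted p = 0.034). Complexes II to V had a median of 0.12 (camera adjusted p = 0.013), and adjusted p = 0.42 with an estimated correlation. SDHD, COX11 (0.97 ± 0.16) and SURF1 (0.80 ± 0.12) were higher, and 4 were higher and 1 lower adjusted over the list alone. The NF-kB list had a median of 0.18 (camera adjusted p = 0.041), and adjusted p = 0.69 with an estimated correlation, with none of its 24 genes past limma on either adjustment and CXCL3 at 1.40 ± 0.39. Ribosomal protein genes had a median of −0.07 (camera adjusted p = 0.025), and adjusted p = 0.43 with an estimated correlation, with 1 of 54, RPS12, lower on either adjustment (−1.21 ± 0.18). These lists depended on single experiments. The NF-kB median was 0.08 without experiment 1 of miR-210 and 0.00 without experiment 2 of miR-34a, where the test's direction turned (camera adjusted p = 0.98 and 0.93). It was 0.52 without experiment 2 of miR-210 and 0.35 without experiment 1 of miR-34a (camera adjusted p = 2.6e-05 and 1.8e-05). The ribosomal median was −0.14 without experiment 2 of miR-210 (camera adjusted p = 0.0058). The list was not called without experiment 1 of miR-210 (0.26) or of miR-34a (0.13), nor complexes II to V without experiment 2 of miR-210 (0.094), or complex I without experiment 1 of miR-34a (0.066, all camera adjusted p).

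The difference passed limma's adjusted p of 0.05 in 1222 rows, 671 higher and 551 lower under miR-34a, and 419 by more than 1 on the log2 scale. Without experiment 2 of miR-210 the count was 716 and without experiment 2 of miR-34a it was 561, and it was 301 with only these 2 groups in the fit.

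Since E2F3 is a reported target of both microRNAs, their ratios were set against those of siE2F3. Between miR-34a and siE2F3, 215 rows were called higher in both and 105 lower in both, where independent lists would share 29.2 and 18.9, and 45 were called in opposite directions (47 from independent lists). Between miR-210 and siE2F3, the counts were 139 higher in both (18.6 from independent lists), 78 lower in both (13.5) and 49 opposite (31.8). Pearson's r across rows, between experiment 1 of one group and experiment 2 of the other, was 0.18 and 0.22 for miR-34a and 0.10 and 0.13 for miR-210. Rows are not independent replicates. Such cross pairs do not share a miR-Neg RNA. For the group means, which do, r was 0.28 for miR-34a and 0.20 for miR-210, and simulated unchanged groups sharing their controls gave 0.12. The covariances were 0.0206 and 0.0128, beside a simulated 0.002. The simulated groups shared 0 calls over 20 draws, but unchanged groups are rarely called at all, so that count is no background for shared calls. The simulated controls held only noise drawn anew in each experiment. A difference carried by the miR-Neg RNA of both experiments is thus missing from that background, and the cross pairs do not remove it either. The control siRNA shared calls too. Across experiments, siCT had an r of 0.07 and 0.13 with miR-210, 0.08 and 0.11 with miR-34a and 0.05 and −0.04 with siE2F3, and of the means 0.20, 0.17 and 0.04. Its covariances of the means were 0.0108, 0.0102 and 0.00171. The r and covariance of miR-210 with siE2F3 (0.20 and 0.0128) were thus close to those of miR-210 with siCT. Rows called higher in both were 39 with miR-210 (2.3 from independent lists), 40 with miR-34a (3.7) and 24 with siE2F3 (1.0). Part of the excess in shared calls may come from the shared controls, which are too few to split.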

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

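The tests of the alike genes, given at the end of this part, were chosen after the result was seen, as was that of a duplex response, while the other tests of the interferon and cell cycle lists were set before. The difference between miR-34a and miR-210 was the contrast that singled out results here. Limma called 152 rows in opposite directions under the 2 microRNAs with their difference called too, 118 of them named genes, 97 higher and 55 lower under miR-34a. Independent lists would give 123.8 opposite calls, and calls in one direction were more numerous, at 405 higher in both (69.6 from independent lists) and 238 lower in both (54.8), with an r of 0.31 between the group means, which share the miR-Neg RNA. The named rows of largest difference were ALDH3A1 (3.11), MMP7 (3.01), SFN (2.96) and ISCU (2.32), higher under miR-34a, and VEGFC (−1.90), SH3PXD2B (−1.89), LMAN2L (−1.72) and NDFIP1 (−1.56), lower under miR-34a. Against miR-Neg, ISCU was at 1.59 under miR-34a, −0.73 under miR-210 and 1.01 in siCT. Its rise against miR-Neg is thus not particular to miR-34a. No explanation of these was tested apart from that of the antioxidant genes under other observations.

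The interferon list was higher under miR-34a by a median of 0.74 over 37 genes. A dye bias would turn the sign between orientations or leave less than 0.2 in one. The medians were 0.88 with the transfected RNA in Cy3 and 0.67 in Cy5 (SE of the median 0.13), both over 0.2, which argues against it. In this part, the SE of a median or mean was taken over genes or rows as if independent. The interferon genes had an estimated correlation of 0.44, so such SEs are too small and do not measure the spread between experiments. A low level in the shared miR-Neg RNA would appear in siCT as well, but miR-34a minus siCT had medians of 0.71 and 0.92 in the 2 experiments (SE 0.16). A response alike to any transfected duplex would cancel against siCT and miR-Neg, which are duplexes too, so the same medians (0.71 and 0.92) argue against it. The bound set before for it, on miR-210 minus siCT (−0.19 and −0.06, SE 0.09), decides nothing, since a shared response cancels there as well. The list was also higher in siE2F3 than in siCT, by 0.57 in experiment 1 and 0.14 in experiment 2 (camera adjusted p = 0.00011, and 0.54 with an estimated correlation). It was not called there without experiment 1 of siE2F3 (0.07, camera adjusted p = 0.40), and 5 of its genes rose adjusted over the list alone, none of them past limma over all genes. This difference rested on 1 experiment, so whether some other duplexes raise the list stays open. An effect of the miR-34a sequence and a property of that duplex preparation, such as an immunostimulatory impurity, remain open too and may be separated only with another preparation.

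Cell cycle genes (98 over both lists) were lower under miR-34a and siE2F3. A dye bias is argued against by medians of −0.52 and −0.70 under miR-34a and −0.28 and −0.39 under siE2F3 in Cy3 and Cy5 (SE 0.06 or lower). A high level in the shared miR-Neg RNA is argued against by the medians minus siCT, −0.64 and −0.62 for miR-34a and −0.52 and −0.24 for siE2F3 (SE 0.06 or lower). No biological explanation of the fall was tested, and growth was not measured here.

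Some genes moved alike in all 4 groups. There were 21 rows higher and 1 lower, EFEMP1, and 14 were named, among them SNRPC (1.07 to 1.49), UBE2V1 (1.31 to 1.69), RDX (0.59 to 1.82), ETF1 (0.74 to 1.47) and ARPC4 (0.71 to 1.23). To test this on one experiment and score it in the other, 34 rows (27 named, 32 higher, 2 lower) were picked for one sign on the 8 arrays of experiment 1 and a size over 0.5 in each group. In experiment 2 they kept shares of 0.77 (miR-210), 0.71 (miR-34a), 0.82 (siE2F3) and 0.75 (siCT) of that size, which argues against noise of a single miR-Neg RNA extract (lowest share 0.71). It is what a difference carried by the miR-Neg RNA of both experiments needs (lowest share 0.71), and an effect of the miR-Neg duplex itself may be its source, though other features common to both miR-Neg RNAs stay open. Among 739 rows picked by siCT alone in experiment 1 (mean size 0.70), the mean in experiment 2, signed by experiment 1, was 0.31 in siCT and 0.11, 0.11 and 0.09 in miR-210, miR-34a and siE2F3 (SE 0.02 or lower).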

How the results depend on the processing

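5 alternatives were chosen after seeing the data: siCT as the control and the fit without the 25% least variable rows, each for lists and named genes, the fit of rows with a gene symbol alone, list medians by experiment, and NDUFA4 counted with complexes II to V, which changed no call of the respiratory chain lists. Counts of changed rows depended on how the spread was estimated. Signal over background is unknown, so no limit from dim probes could be given. No value was missing, so a looser rule on missing values moved nothing, and seed sites were not run. Median centring, robust moderation and single probes kept every count within 1.5 times. With all 16 arrays in the fit limma called 4023 rows in miR-210, 4812 in miR-34a, 2422 in siE2F3, 1040 in siCT, 1797 in siE2F3 against siCT and 2868 in miR-34a against miR-210. On the Cy3 arrays it called 1125, 214 and 3 rows in miR-210, siE2F3 and siCT, 451 in miR-34a against miR-210 and 0 in siE2F3 against siCT (2730 with an unadjusted p under 0.05). On the Cy5 arrays it called 69 in siE2F3 against siCT and 736 in miR-34a against miR-210. With the compared groups alone it called 788 in miR-34a, 301 in miR-34a against miR-210, and 0 in miR-210, siE2F3, siCT and siE2F3 against siCT (4153, 3994, 2774 and 3650 with an unadjusted p under 0.05), where fewer replicates estimate the spread. Without moderation the counts were 489, 1073 and 89 in miR-210, miR-34a and siE2F3, 34 in miR-34a against miR-210, and 0 in siCT and siE2F3 against siCT (2526 and 3089 with an unadjusted p under 0.05).

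With scaled arrays limma called 281 in siCT and 525 in siE2F3 against siCT. With quantile normalization it called 1246, 406, 733 and 745 in siE2F3, siCT, siE2F3 against siCT and miR-34a against miR-210. With the experiment as a replicate block it called 128 in siCT, and the other counts stayed within 1.5 times. With rows with a gene symbol alone it called 121 in siCT. With siCT as the control it called 438 in miR-210 and 986 in miR-34a. Without single replicates the counts ranged from 754 to 1223 in miR-210, 1094 to 1801 in miR-34a, 143 to 432 in siE2F3, 0 to 284 in siCT, 0 to 254 in siE2F3 against siCT and 561 to 875 in miR-34a against miR-210. Such fits assume that the lone replicate varies like the other groups. Both counts of 0 are from limma without experiment 2 of siCT (1804 and 2530 with an unadjusted p under 0.05). Correlations within an experiment, which share the miR-Neg RNA, moved from those across experiments to 0.27 for miR-34a and siE2F3 in experiment 1, and to 0.14 and 0.21 for miR-210 and siE2F3. Turning all arrays makes E2F3 in siE2F3 1.19.

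Among 4794 alternative values of the 299 named values past the threshold, 1180 no longer passed and 1 turned, MXI1 under siE2F3 at 0.33 on the Cy3 arrays. With an estimated correlation none of the 42 called list results passed in camera, whose medians stay as they are. These were, in miR-210, 0.08 for the miR-34a target list, −0.17 for miR-210 targets, −0.12 for interferon, 0.18 for NF-kB and 0.21 for cholesterol. In miR-34a they were −0.50 for G1/S, −0.66 for G2/M, 0.32 for p53, −0.15 for miR-34a targets, 0.12 for complex I, 0.17 for complexes II to V, 0.24 for iron, 0.19 for hypoxia, 0.74 for interferon and 0.31 for NF-kB. In siE2F3 they were −0.24 for the E2F family, −0.29 for G1/S, −0.36 for G2/M, 0.25 for complex I, 0.20 for complexes II to V, 0.14 for iron and 0.28 for interferon, and in siCT 0.18 for stress. In siE2F3 against siCT they were −0.27 for the E2F family, −0.25 for G1/S, −0.47 for G2/M, 0.28 for complex I, 0.20 for complexes II to V, 0.35 for interferon, −0.19 for cholesterol and −0.25 for stress. In miR-34a against miR-210 they were −0.49 for G1/S, −0.69 for G2/M, 0.42 for p53, −0.23 for miR-34a targets, 0.13 for miR-210 targets, 0.14 for complex I, 0.12 for complexes II to V, 0.25 for iron, 0.90 for interferon, 0.18 for NF-kB and −0.07 for ribosomal proteins.

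Other settings changed some list calls, given here with the median. Here and in the next paragraph, epithelial stands for the epithelial and mesenchymal list. It holds markers of both states, so the sign of its median speaks for neither. With all 16 arrays, calls were gained by hypoxia in miR-210 (0.08), epithelial (0.11) and ribosomal (−0.09) in miR-34a, epithelial in siE2F3 (−0.05), ribosomal in siE2F3 against siCT (0.06) and the E2F family in miR-34a against miR-210 (−0.22), and lost by interferon in miR-210 (−0.12) and NF-kB in miR-34a against miR-210 (0.18). On the Cy3 arrays they were gained by cholesterol in siE2F3 (−0.13) and G2/M in siCT (0.11), and lost by interferon (−0.14) and NF-kB (0.20) in miR-210, iron in siE2F3 (0.14) and ribosomal in miR-34a against miR-210 (−0.09). On the Cy5 arrays they were gained by ribosomal in miR-34a (−0.09), iron (0.16) and ribosomal (0.07) in siE2F3 against siCT and the E2F family in miR-34a against miR-210 (−0.17). There they were lost by miR-34a targets in miR-210 (0.06), complex I in miR-34a (0.01), the E2F family in siE2F3 (−0.07), stress in siCT (0.12) and cholesterol in siE2F3 against siCT (−0.15). With the compared groups alone they were gained by stress in miR-210 (0.19), the E2F family in miR-34a (−0.23) and in miR-34a against miR-210 (−0.22) and ribosomal in siE2F3 against siCT (0.06), and lost by NF-kB in miR-34a against miR-210 (0.18). With siCT as the control the E2F family gained a call in miR-34a (−0.31), and in miR-210 it was lost by miR-34a targets (0.10), miR-210 targets (−0.06), interferon (−0.14), NF-kB (0.11) and cholesterol (0.22). With scaled arrays ribosomal gained one in miR-34a (−0.08) and NF-kB lost one in miR-34a against miR-210 (0.14), and with quantile normalization the E2F family gained one there (−0.22). With the experiment as a replicate block calls were gained by ribosomal in miR-34a (−0.09), cholesterol in siE2F3 (−0.14) and iron in siE2F3 against siCT (0.18), and no other list call changed. Without the 25% least variable rows they were gained by epithelial (0.17) and ribosomal (−0.24) in miR-34a, ribosomal in siCT (−0.20), and iron (0.20) and ribosomal (0.23) in siE2F3 against siCT. There they were lost by complex I in miR-34a (0.12), cholesterol in siE2F3 against siCT (−0.27), and NF-kB (0.17) and ribosomal (−0.20) in miR-34a against miR-210. Apart from the turned values named here, directions of called results were kept in these settings. The cause was not tested.

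Without single replicates, medians of lists whose call changed ranged as follows. In miR-210 they ranged from 0.09 to 0.11 for miR-34a targets, 0.01 to 0.26 for hypoxia, −0.22 to −0.10 for interferon, 0.22 to 0.28 for cholesterol and 0.02 to 0.53 for NF-kB. In miR-34a they ranged from 0.07 to 0.15 for complex I, 0.12 to 0.27 for hypoxia, −0.24 to −0.19 for the E2F family, 0.13 to 0.55 for NF-kB, 0.03 to 0.17 for epithelial and −0.07 to −0.05 for ribosomal. In siE2F3 they ranged from −0.27 to −0.06 for the E2F family, 0.15 to 0.17 for iron, 0.01 to 0.65 for interferon, −0.19 to −0.04 for cholesterol and 0.02 to 0.08 for ribosomal. In siE2F3 against siCT they ranged from −0.38 to −0.13 for G1/S, 0.07 to 0.60 for interferon, −0.23 to −0.13 for cholesterol, −0.32 to −0.20 for stress, 0.02 to 0.08 for ribosomal and 0.14 to 0.22 for iron. In miR-34a against miR-210 they ranged from 0.00 to 0.52 for NF-kB, −0.14 to −0.06 for ribosomal, −0.36 to −0.16 for the E2F family, 0.08 to 0.12 for complexes II to V, −0.06 to 0.19 for hypoxia, 0.10 to 0.15 for complex I and −0.03 to 0.16 for epithelial. There the NF-kB test turned without experiment 1 of miR-210 (0.08) and without experiment 2 of miR-34a (0.00).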

Other observations

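The tests of the antioxidant genes were chosen after part of the result was seen, and the lists in the next paragraphs were set before the data were examined. Under miR-210, the epithelial and mesenchymal list had 1 gene that rose and 2 that fell of 30 measured (median 0.05, camera adjusted p = 0.76). SNAI1, a repressor of epithelial genes, rose by 0.90 ± 0.09, and the adhesion genes EPCAM (−0.88 ± 0.13) and CDH1 (−0.80 ± 0.13) fell. CDH1 was higher under miR-34a than under miR-210 by 1.38 ± 0.18 and SNAI1 lower by −0.83 ± 0.13, both past limma's adjusted p of 0.05 for the difference. Under miR-34a, 7 genes of that list rose and 1 fell (median 0.11, camera adjusted p = 0.074), CLDN1 (1.04 ± 0.21) and S100A4 (1.0 ± 0.1) among those that rose. With an estimated correlation the list had a camera adjusted p of 0.29 under miR-34a, and its median was 0.17 without experiment 2 of miR-34a. Under siE2F3, COL4A1 (−1.12 ± 0.20), VIM (−0.86 ± 0.11) and CDH1 (−0.65 ± 0.13) fell and none rose past the limma threshold (median −0.05, camera adjusted p = 0.12).

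In the microRNA machinery list, the processing enzyme gene DICER1 rose under miR-210 (1.21 ± 0.09) and PRKRA, which binds it, fell (−0.55 ± 0.12), with a list median of 0.01 over 14 genes (camera adjusted p = 0.98). DICER1 was lower under miR-34a than under miR-210 by −0.92 ± 0.13 (limma adjusted p = 0.013). In the stress response list, the transcription factor gene XBP1 (−1.14 ± 0.15) and the amino acid transporter gene SLC7A5 (−1.14 ± 0.15) fell and DDIT3 rose (1.08 ± 0.15) under miR-34a, with 4 genes that rose and 2 that fell of 28 (median 0.01, camera adjusted p = 0.79). Under miR-210, DNAJB9 (0.86 ± 0.15) and the chaperone gene HSPA5 (0.70 ± 0.12) rose and SDF2L1 fell (−0.80 ± 0.10), with a median of 0.19 (camera adjusted p = 0.15). Of 54 ribosomal protein genes, 5 fell and none rose past the limma threshold under miR-34a, with RPS12 lowest (−1.31 ± 0.13). The list median was −0.09 (camera adjusted p = 0.058), and adjusted p = 0.51 with an estimated correlation. Without experiment 2 of miR-34a the median was −0.05. At the preset correlation the list was called with the experiment as a replicate block (median −0.09, camera adjusted p = 0.047). In the cholesterol list under miR-34a, 5 rose and 1 fell of 20 (median 0.04, camera adjusted p = 0.23), with IDI1 at 1.36 ± 0.17. The cell cycle lists were not called under miR-210, with medians of 0.06 for G2/M (camera adjusted p = 0.78) and −0.01 for G1/S (0.98), and p53 targets had a median of −0.05 there (0.35). Medians of the blood and immune cell markers ranged from −0.01 to 0.08 over the 6 comparisons, and those of the fibroblast and endothelial markers from −0.03 to 0.03, and neither list was called by camera in any of them (lowest adjusted p = 0.37 and 0.73).

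As a hypothesis of these data, target genes of the antioxidant transcription factor NRF2 may move as a group between the microRNAs, since HMOX1 and ALDH3A1 lay far apart. A list of 31 such genes was written from textbook knowledge, of which 29 were measured and 11 had been seen before the test. Over the 18 others, the median of miR-34a minus miR-210 was 0.32 in experiment 1 and 0.48 in experiment 2. Its SE, taken over genes as if independent, was 0.24. The lower value of 0.32 does not clear the bound of 0.2 by that error, so the test leaves the hypothesis open. Of these 18 genes, 2 were higher and none lower past limma's threshold for the difference, 1 rose and 4 fell under miR-210 and 5 rose and none fell under miR-34a. The median over all 29 genes, which includes those that prompted the idea, was 0.92.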
